A study of Mus musculus with 3 samples.

How the data were processed

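HIF1A, the oxygen-regulated subunit of hypoxia-inducible factor 1, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in melan-Ink4a-Arf-null cells, an immortalized mouse melanocyte line that lacks functional Cdkn2a. Per the labels' protocols, cells were kept in 1% oxygen for 24 hours, crosslinked for 9 minutes in 1% formaldehyde and sonicated. The labels also list 10% serum, 200 nM of the phorbol ester TPA and 200 pM cholera toxin for every sample. Chromatin was precipitated with 10 µg of an anti-HIF1A antibody, and gel-purified DNA of 200 to 500 bp was made into Illumina libraries. The samples described here are 2 HIF1A ChIP samples, numbered replicates 1 and 2 in the labels, and 1 input sample. Nothing in the labels says that the replicates came from separate cultures, so the spread between them may be technical. A peak list was analysed for each ChIP sample, and no file of the input was used here.

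The authors called peaks separately for each ChIP library with MACS in Galaxy, per the file headers, and both headers name the same control file. The submitters' processing notes name MACS 1.4.2 and the mouse build mm9, and the headers give no version. The aligner is not given in the sources used here. The settings in both headers were a p-value threshold of 1e-05, a tag size of 25 bp, a band width of 300 bp, a model fold of 10 and an effective genome size of 1.87 Gb. Local background was taken over the peak region and over 1000, 5000 and 10000 bp, per the file headers. The fragment size estimated by the caller was 68 bp for replicate 1 and 53 bp for replicate 2. Both lie below the 200 to 500 bp of the gel-purified DNA, and the reason was not examined. Each deposited list gives the position of every peak, an offset to its summit and the raw count of ChIP tags in it. It also gives 10 times the -log10 p-value (called the p-based score below), the fold enrichment over local background and a false discovery rate in percent, all made by the authors' caller. The p-based score has a ceiling: 10 peaks of replicate 1 and 4 of replicate 2 stand at exactly 3100, and 1 peak of replicate 1 lies above it. These values are the authors' own for each peak and were used to rank, filter or describe peaks within a list. Levels were not compared between the lists, which differ in depth and fragment size. Where values of a paired site are given for both replicates, they describe the site in each list.

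Depth was high: per the file headers, replicate 1 had 94716495 tags (80.3% unique), replicate 2 had 103139204 (84.3% unique) and the control had 66.4% unique tags. Counts per region in the control were not used here. Intervals on shares of peaks are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only.

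Positions are given in mm9, counted from 1. Peak length equals end minus start plus 1 in every row, and the summit position is start plus the offset. The reference table at hand describes GRCm38, while the submitters' processing notes name mm9, so peaks were not assigned to genes. The planned tests of transcription start sites and of 12 gene lists fixed before the data were examined were not run. The planned motif tests, including the HIF core motif, were not run for want of an mm9 sequence. Only the number of protein-coding genes per chromosome was taken from the GRCm38 table.

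A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and the counts were checked with bedtools 2.31.1. The chance level came from 1000 circular shifts of replicate 2's peaks along each chromosome, wrapped at the span that the peaks of both lists cover (one-sided permutation test, smallest possible p = 0.001). Mutual best overlaps gave 1742 pairs, used to compare strength and summit position. Medians of shared and unshared peaks were compared with two-sided permutation tests of 100000 resamples (10000 for tags and lengths), as were the correlations, which run across peaks and not across samples. Benjamini-Hochberg adjustment was made over 8 tests of shared against unshared peaks and, separately, over 8 correlations. The chance level of overlap inside the X block came from 1000 shifts of replicate 2's peaks within it. Random summits were drawn 1000 times within the paired peaks. The number of shared regions per chromosome was compared with gene number by 100000 multinomial draws. Peak-dense windows, defined after the data were seen, are the 1 Mb windows with at least 8 peaks in either list, of which there were 40. The areas described on chromosomes X, 4 and 13, also defined after the data were seen, are runs of at least 3 adjacent windows with at least 10 peaks each in either list. The rule for named peaks, fixed before the data were examined, took the 25 pairs with the best mean rank of fold and the 3 peaks of highest fold found in only 1 list, for each replicate. At most 12 pairs are described in full. Alternatives covered the overlap rule, stricter thresholds, equal list lengths, the p-based score in place of fold, peak centres in place of summits and each replicate alone.

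The overlap search was tested on simulated lists of 3055 and 2680 peaks. With 1500 peaks placed in both lists it found 1503 and 1501 shared, and with unrelated lists it found 6 in each. Positions were drawn evenly along autosomes, without packed windows, so the chance level in such windows was not checked this way. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used matplotlib 3.10.9.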

Results

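To map where HIF1A sits on chromatin in hypoxic melanocytes, the study sequenced DNA precipitated with an anti-HIF1A antibody from melan-Ink4a-Arf-null cells held in 1% oxygen for 24 hours. There were 2 ChIP replicates and 1 input, and no normoxic sample was analysed here. The comparison the peak lists allow is therefore of replicate with replicate, each called against the same control. The ChIP libraries held 94716495 tags in replicate 1 and 103139204 in replicate 2. Replicate 1 had 3055 peaks covering 2053 kb, with a median length of 559 bp. Replicate 2 had 2680 peaks covering 1285 kb, with a median length of 366.5 bp. Tags inside peaks made up 0.486% of all tags of replicate 1 and 0.336% of those of replicate 2. Fold enrichment over local background had a median of 5.32 in replicate 1 (range 2.38 to 39.43) and 5.68 in replicate 2 (range 1.96 to 29.61).

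The site with the highest fold in both lists combined lay on chromosome 3, at 122967209 to 122968159 in replicate 1 and 122967283 to 122968034 in replicate 2. It was enriched 39.43-fold with 528 tags in replicate 1 and 25.68-fold with 444 tags in replicate 2, and its summits were 7 bp apart. A pair of sites on chromosome 9 followed. The first, at 13338448 to 13339506, reached 31.81-fold and 22.31-fold in replicates 1 and 2, and the second, at 44728679 to 44729755, reached 30.64-fold and 22.37-fold. Their summits differed by 18 and 27 bp. On chromosome 8, the site at 32297257 to 32298404 had 25.23-fold and 18.65-fold enrichment in the respective replicates, and the site at 47636719 to 47637799 had 20.19-fold and 15.34-fold. The site at 26919296 to 26920608 on chromosome 19 was enriched 23.73-fold in replicate 1 and 16.73-fold in replicate 2, with summits 1 bp apart. On chromosome 4, the site at 108952160 to 108953268 had 20.77-fold and 15.01-fold enrichment, and on chromosome 16 the site at 86820944 to 86821563 had 20.97-fold and 17.44-fold. Start and end positions of these sites are those of replicate 1 in build mm9. No gene is assigned to them, because the gene table at hand describes another build.

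The 25 pairs ranked highest by fold lay on 15 chromosomes, 19 of them on autosomes, 5 on X and 1 on Y. The 8 sites above carried between 237 and 728 tags in replicate 1, whereas several narrow ones carried few. The site at 53226909 to 53227232 on chromosome X had 61 and 77 tags at 19.16-fold and 27.18-fold in replicates 1 and 2. The site at 12634745 to 12635045 on chromosome 1 had 49 and 79 tags at 15.91-fold and 29.61-fold. Ranking the pairs by the p-based score instead, a choice made after the data were seen, kept 10 of the 25, and 24 of the 25 were then autosomal. The sites at the ceiling of that score in both lists were the pair on chromosome 9, a chromosome 4 site at 133311747 to 133314068 with 1554 and 1078 tags and a chromosome 8 site at 86422200 to 86424285 with 1757 and 1169 tags.

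Of replicate 1's peaks, 1774 overlapped a peak of replicate 2, which is 58.1% (95% interval 56.3 to 59.8%). Of replicate 2's peaks, 1935 overlapped a peak of replicate 1, which is 72.2% (70.5 to 73.9%). Shifted peak positions gave 0.273% ± 0.462 and 0.361% ± 0.643 (SD over 1000 shifts), and the highest shifted values were 6.51% and 9.03%. The excess had a permutation p of 0.001 for each list, the smallest the shifts can give. Both lists were called against the same control library, so part of the overlap may come from the control. Outside peak-dense windows (1 Mb windows with at least 8 peaks in either list, defined after the data were seen), 43.3% of replicate 1's peaks and 76.5% of replicate 2's overlapped a peak anywhere in the other list.

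Sharing rose with the p-based score in both lists. In replicate 1 it went from 32.6% in the lowest quintile to 90.0% in the highest, and in replicate 2 from 43.5% to 98.9%. At scores of 800 and above, all 131 peaks of replicate 1 and all 64 of replicate 2 were shared. Shared peaks of replicate 1 also had higher fold than unshared ones, with medians of 6.29 and 4.37 (difference 1.92, 95% bootstrap interval 1.70 to 2.08, permutation p = 1e-05, the smallest possible, adjusted p = 2.7e-05 over 8 tests). In replicate 2 the medians were 5.68 and 5.72, and the difference of -0.04 (-0.36 to 0.08) did not pass the permutation test (p = 0.461, adjusted p = 0.461). Outside peak-dense windows it was -2.275 (-2.64 to -1.76, permutation p = 1e-05, the smallest possible), so unshared peaks there had the higher fold. Inside them, with 1618 of the 2680 peaks, shared peaks had the higher fold, with medians of 6.29 and 5.57 (difference 0.72, 0.48 to 1.04, permutation p = 1e-05). The tests and intervals treat peaks as independent, which closely packed ones may not be, and 925 of the 1618 lay in the X block. Unshared peaks of replicate 2 were short and thinly covered, with a median of 38 tags over 229 bp against 95 tags over 445 bp for shared ones (permutation p = 1e-04 for tags and for length, the smallest possible there).

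**Figure D1:**
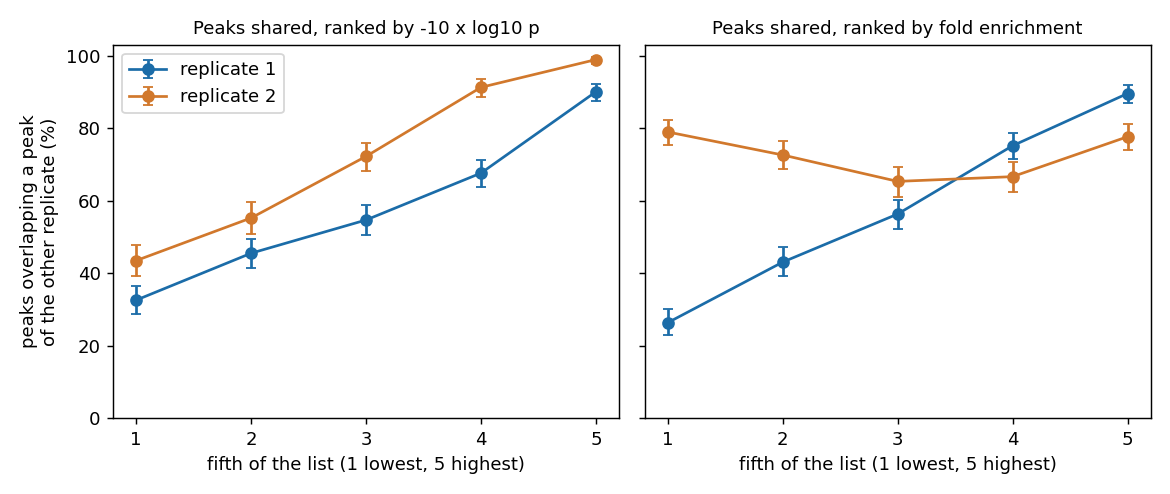
Percent of peaks that overlap a peak of the other replicate (y axis) by quintile of the list (x axis, 1 lowest to 5 highest), ranked by the p-based score at left and by fold enrichment at right; points are the 2 replicates and bars are exact 95% binomial intervals. By score, sharing climbs to 90.0% in replicate 1 and 98.9% in replicate 2; by fold it climbs only in replicate 1, while replicate 2 stays between 65.3% and 78.9%.

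Among the 1742 paired peaks, summits lay a median of 25 bp apart (quartiles 7 and 92.8 bp) and 63.9% of pairs were within 50 bp. Random positions inside the same peaks gave a median of 156 bp (permutation p = 0.001, the smallest possible). Peak centres, which hold no summit information, were already a median of 41 bp apart. Random positions therefore do not give the distance expected without agreement of summits, and that distance was not estimated. Fold enrichment correlated across pairs, with Spearman's rho of 0.59 and Pearson's r of 0.62, and tags with rho of 0.84 and r of 0.94. For fold, both permutation p-values were 1e-05 (adjusted 2e-05 over 8 correlations), and for tags both were 1e-04 (adjusted 1e-04), the smallest possible in each case. The rho of fold was 0.68 outside peak-dense windows and 0.62 inside them. Peaks are not independent replicates, and these p-values concern the 2 libraries only.

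**Figure D2:**
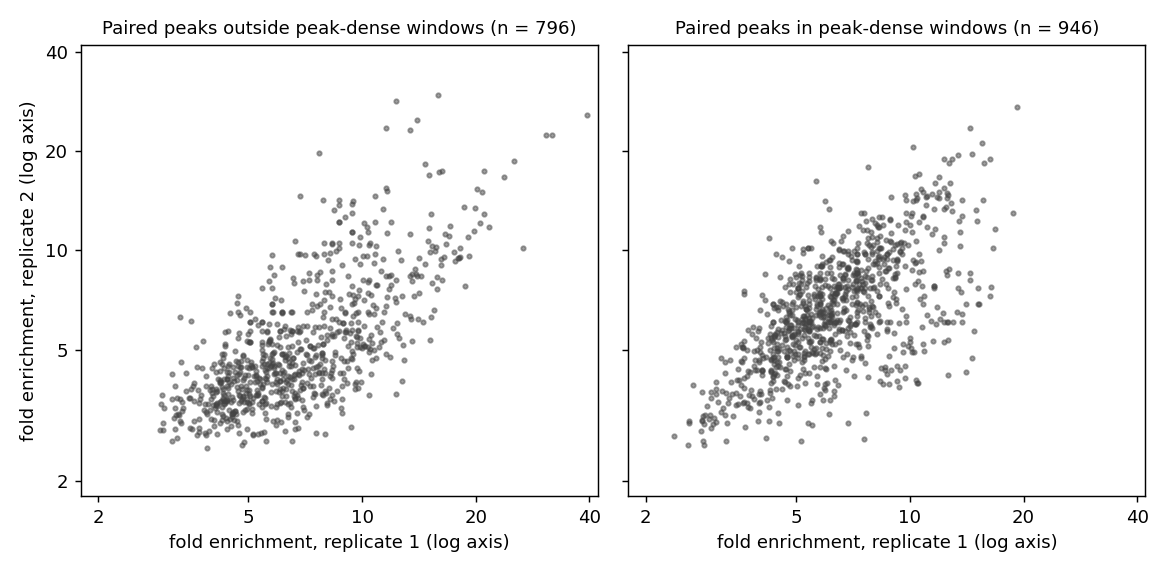
Fold enrichment of paired peaks in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, outside peak-dense windows (left, n = 796) and inside them (right, n = 946); each point is a pair. Fold in the lists rises together in both panels, with Spearman's rho of 0.68 outside the windows and 0.62 inside them.

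Chromosome X held a larger share of sites than of genes. Merging overlapping peaks of both lists gave 1721 shared regions, of which 606 (35.2%, 95% interval 33.0 to 37.5%) were on X, a chromosome with 4.41% of protein-coding genes. This was 7.98 times the number expected from gene count. A chi-square test over all 21 chromosomes gave p = 1e-05 by multinomial draws, the smallest possible. The draws treat regions as independent, which closely packed regions may not be. Most of the X peaks lay in a block between 120 and 123 Mb, which contained 619 of the 725 X peaks of replicate 1 (20.3% of its list) and 925 of the 1055 of replicate 2 (34.5%). Of these, 92.7% and 73.5% were shared. Their median fold was 6.05 in replicate 1 and 6.50 in replicate 2. Chromosome Y held 69 and 97 peaks of replicates 1 and 2, and the stretch from 145 to 148 Mb on chromosome 4 held 100 and 161. Outside the 40 peak-dense windows, 21 of 796 shared regions (2.64%, 1.64 to 4.0%) were on X, as were 55 of 1844 peaks of replicate 1 (2.98%, 2.25 to 3.86%) and 53 of 1062 of replicate 2 (4.99%, 3.76 to 6.48%). Every Y peak lay inside the windows, and the expected numbers still count the genes in them. Outside the windows, chromosome 1 held 64 shared regions (1.46 times the gene-based number) and chromosome 17 held 24 (0.623 times).

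**Figure D3:**
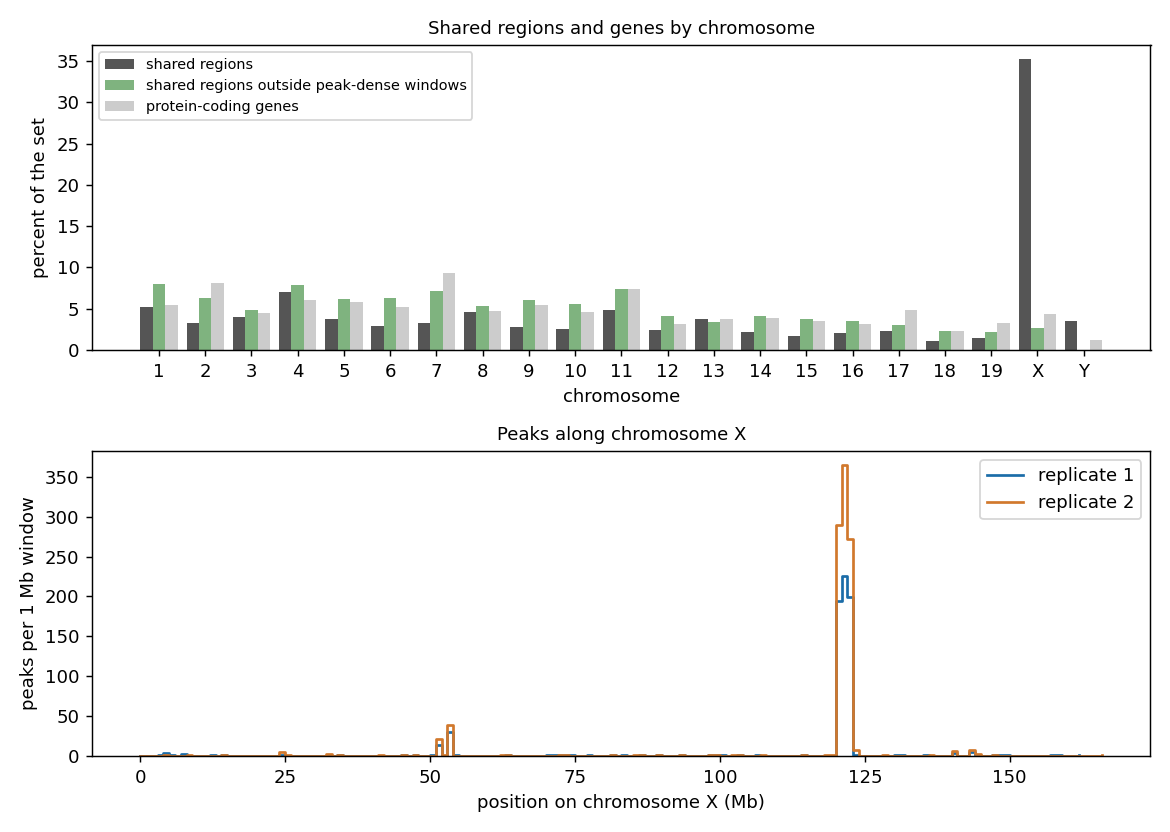
Top, percent of shared regions, of shared regions outside peak-dense windows and of protein-coding genes (y axis) by chromosome (x axis); bottom, peaks per 1 Mb window (y axis) along chromosome X (x axis, Mb) in each replicate. X holds 35.2% of shared regions and 2.64% of those outside peak-dense windows, and the peaks of X stand mostly between 120 and 123 Mb.

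A stretch of chromosome 13 held the peaks of highest fold among those called in replicate 1 alone. From 21 to 24 Mb, replicate 1 had 85 peaks (2.78% of its list) with a median fold of 9.52, and replicate 2 had 42 (1.57%) with a median of 6.08. All 42 peaks of replicate 2 were shared, and 37 of replicate 1's were (43.5%, 32.8 to 54.7%). The 3 peaks of highest fold found only in replicate 1 all lay here, at 23618154 to 23618575 (13.74-fold, 101 tags), 22027165 to 22027612 (13.01-fold, 80 tags) and 21946978 to 21947446 (12.29-fold, 91 tags). The nearest peaks of replicate 2 were 3520, 4446 and 326 bp away, in that order. The 3 of highest fold found only in replicate 2 were narrow: 45008047 to 45008203 on chromosome 1 (18.25-fold, 46 tags), 104736152 to 104736321 on chromosome 14 (17.04-fold, 44 tags) and 166096798 to 166096975 on chromosome 1 (13.39-fold, 41 tags).

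The caller's false discovery rates were high. In replicate 1 they were 100% for 1659 peaks (54.3%) and at most 25% for 218, and in replicate 2 they were 100% for 1467 peaks (54.7%) and at least 58.72% for every peak. In this caller the rate is understood as the number of calls with ChIP and control exchanged over the number of peaks, at the same score or above. The headers do not state this, but rate times rank was whole to within 0.1 for 98.2% of the 1396 replicate 1 peaks under 100%, and for 98.0% of the 1213 in replicate 2, where evenly spread values would give 20%. Read so, scores of 400 and above comprised 323 peaks and 89 exchanged calls in replicate 1, and 195 peaks and 126 exchanged calls in replicate 2. At 1600 and above the numbers were 48 and 6 in replicate 1, and 24 and 16 in replicate 2. The ratio of peaks to exchanged calls thus went from 2.52 at 200 to 8 at 1600 in replicate 1, and from 1.61 to 1.5 in replicate 2. High rates were not confined to weak peaks. In replicate 2 the rate was 100% at both chromosome 9 sites, at 26919296 on chromosome 19 and at 47636719 on chromosome 8. The other sites listed first, on chromosomes 3, 4, 8 and 16, had 66.67 to 90% there. In replicate 1 all of these sites had 15.79 to 23.08%.

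**Figure D4:**
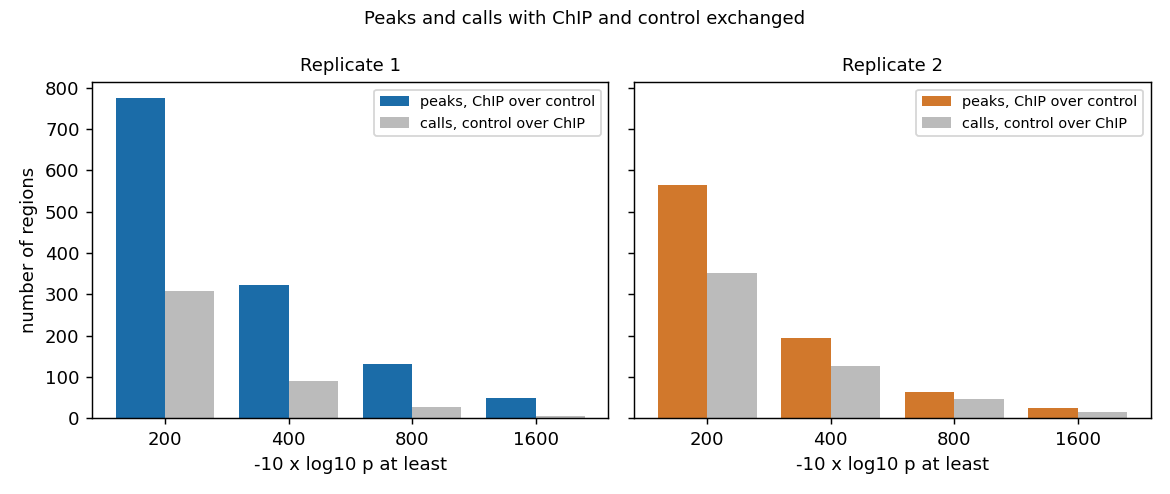
Number of regions (y axis) at or above each p-based score (x axis) in replicate 1 (left) and replicate 2 (right); coloured bars are peaks of ChIP over control, and grey bars are calls with ChIP and control exchanged, as implied by the deposited rates. At 800 and above, replicate 1 has 131 peaks and 26 exchanged calls, and replicate 2 has 64 and 47.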

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

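The outside-window settings were chosen after the data were seen. The share of peaks found in both lists stayed above the shifted level under every overlap rule and threshold run, from 40.2 to 62.6% in replicate 1 and from 47.1 to 76.4% in replicate 2. The number of shared peaks fell to 901 and 970 in replicates 1 and 2 with the best 50% by p-based score. It was 115 and 121 with a fold of at least 10, and 798 and 811 outside peak-dense windows with both lists restricted to peaks there. Fewer peaks were compared in each case, but the share also fell at a fold of at least 10, to 40.2% and 47.1%, with both lists cut at that fold. Against the whole other list, 99 of replicate 1's 100 peaks of highest fold and 95 of replicate 2's were shared. Outside the windows the share was 43.3% in replicate 1 and 76.4% in replicate 2. A threshold of 1% FDR could not be used, because 1 peak of replicate 1 and 0 of replicate 2 met it. The difference in strength between shared and unshared peaks of replicate 2 depended on the measure and the windows: against -0.04 for fold, it was 58.91 with the p-based score and -2.275 for fold outside peak-dense windows (permutation p = 1e-05 for both, the smallest possible), and the cause of the first was not tested. The share on chromosome X was 23.7% of replicate 1's peaks (without replicate 2) and 39.4% of replicate 2's (without replicate 1). Outside peak-dense windows, which removes the X block by construction, it was 2.64% of shared regions, 2.98% of replicate 1's peaks and 4.99% of replicate 2's, against 4.41% of genes with those in the windows still counted, so the direction turned for shared regions and replicate 1's peaks, while the interval of replicate 2's (3.76 to 6.48%) held the share of genes. The correlation of fold across pairs (0.56 to 0.68) and the summit distance (23 to 41 bp, the highest with peak centres) kept their calls under the alternatives run. Chromosome length was not run as an expectation, nor were the start-site, gene-list and motif alternatives, for want of an mm9 reference. No paired analysis was possible because 1 group alone has replicates. The effect of depth on sharing was not tested, since no reads were used, and a site listed in 1 replicate may lie just under the caller's threshold in the other.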

Other observations

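The definitions of peak-dense windows and of the X block were chosen after the results were seen. So were the tests of single-library noise, of peaks of 300 to 600 bp and of quintiles with at least 20 unshared peaks. The final verdicts on control coverage, a single copy of X, repeated copies and few tags were also chosen then. Some smaller groups of closely packed sites recurred in both replicates. Others did not: on chromosome 5, 14 to 15 Mb held 2 peaks of replicate 1 and 8 of replicate 2, with 0 shared. On chromosome X, the window from 53 to 54 Mb held 30 peaks of replicate 1 (median fold 9.13, 45.5 tags) and 39 of replicate 2 (9.33, 43 tags), and that from 51 to 52 Mb held 14 and 22. On chromosome 8, 19 to 20 Mb held 21 and 35 peaks at low fold (medians 4.15 and 4.52) but high tags (310 and 233). On chromosome 3, 25 to 26 Mb held 22 and 23 peaks, with median folds of 3.37 and 3.82. The window from 87 to 88 Mb on chromosome 11 held 8 and 7 peaks with median folds of 9.05 and 6.07. Among the 100 peaks with the highest p-based score, 5 of replicate 1 and 21 of replicate 2 lay in the X block. The block held 20.3% and 34.5% of the whole lists, so it was under-represented among these peaks.

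The first pattern is the block of X from 120 to 123 Mb. Noise of single ChIP libraries is argued against, since 92.7% (90.4 to 94.6%) of replicate 1's peaks and 73.5% (70.5 to 76.3%) of replicate 2's there were shared. Shifting replicate 2's peaks within the block gave means of 23.8% and 19.1% and highest values of 53.0% and 43.0% (permutation p = 0.001 for both, the smallest possible). Noise of the control library cannot be judged this way, because both lists were called against the same one. The next 2 explanations were examined through an implied background, tags per kb over fold, which was not read from the control. Its median was below the genome mean of ChIP tags in the block (0.711 and 0.723 times) and outside the windows (0.917 and 0.938 times). Whether it follows the caller's local background was not tested, so these ratios alone cannot decide either explanation. A single copy of X missed its planned prediction. Implied background in the block was 1.35 times (1.21 to 1.46) and 1.37 times (1.25 to 1.66) that of the 55 and 53 X peaks outside peak-dense windows. Peak lengths were not matched there. A single copy would hold along all of X, yet 619 of replicate 1's 725 X peaks and 925 of replicate 2's 1055 lay in the block. Outside peak-dense windows X held 2.98% and 4.99% of the peaks of replicates 1 and 2, against 4.41% of genes. This concentration argues against a single copy as the source of the block. Low control coverage met its planned prediction, with implied background 0.775 times (0.733 to 0.799) and 0.771 times (0.729 to 0.823) that of peaks outside the windows. Among peaks of 300 to 600 bp it was 0.857 and 0.700 times. Low coverage is left open because the X peaks outside the windows lay lower still and called peaks alone were seen. Repeated copies of one sequence missed their planned prediction, which asked for both replicates: the most frequent summit distance held 149 pairs in replicate 2 (10800 to 11000 bp), above the highest of 1000 orders of the same gaps (143), but 68 in replicate 1 (129200 to 129400 bp), within them (79). They are left open rather than excluded, because 68 was not below the mean of those orders (61.2, permutation p = 0.062), though the distances differed between replicates, and no biological explanation was tested.

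The second pattern is that fold was not higher in shared than in unshared peaks of replicate 2 over the whole list. Peak-dense windows are argued against as its source, since outside them the difference was -2.275 (-2.64 to -1.76), while inside them, with 1618 of the 2680 peaks, shared peaks had the higher fold by 0.72 (0.48 to 1.04). A candidate explanation is that unshared peaks have few tags and pass the caller's threshold only at high fold. The planned test met that prediction, with a difference of 0.409 (-0.039 to 0.774) averaged over quintiles of tags, but 3 of those quintiles held 11, 9 and 7 unshared peaks, and without them, with 223 of the 250 unshared peaks, it was -1.0 (-1.86 to -0.105). Few tags are therefore left open, and whether these sites bind HIF1A was not tested.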
